A study of Drosophila melanogaster with 19 samples.

How the data were processed

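RNA was measured in Drosophila S2R+ cells, a line derived from embryos that carries features of blood cells, after treatment with double-stranded RNA (dsRNA) for 4 days at 25 °C. Per the labels' protocols the dsRNA was given at 30 μg/ml in medium without serum and brought to 10 μg/ml with medium holding 10% serum. RNA was selected with oligo-dT and sequenced as read pairs of 100 bp. The RNA samples fell into 5 groups by their labels, with 2 libraries each for dsRNA against GFP (the control), mip40, mip120 and mip130 and 1 library for dsRNA against E2F2. The series also lists 9 samples of nuclease-digested chromatin and 1 of naked DNA, which were not analysed here.

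The authors deposited FPKM values (fragments scaled to transcript length and to the number of mapped fragments) for 37161 transcripts in 9 columns, 1 per RNA library. The submitters' processing notes name Bowtie 1.1.1, TopHat2 2.0.12, Cufflinks and Cuffnorm. The genome build, the annotation release and the settings of these tools are not given in the sources used here, nor is the strand setting of the libraries. Positions are given as in the table. On chromosome 3R, gene starts in the table lay a median of 4174278 bp from those of Release 6 over 2779 genes matched by symbol, so no position was taken from Release 6. Of 15021 gene symbols, 11618 were current in the reference tables, 3285 were found there as older names and 118 were not found, while 6 symbols in the table had turned into dates. The table's 4 columns of group means were not used, since 736 of their cells held errors and 2895 departed from the mean of their libraries by more than 0.1%.

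FPKM hold no counts of reads, whole reads could not be recovered from them, and sequencing depth is therefore unknown. No test of counts could be run. The scaling between libraries is that of the deposited values. An exact 0 in the table can be a failed estimate, so a gene at 0 throughout a group is described as listed at 0, with the value of each library and no fold.

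Each gene's value was the sum of the FPKM of its transcripts in the classes of known transcripts (30453), new isoforms of known genes (5792) and other overlaps on the gene (176). The 604 transcripts of no annotated gene and the 136 antisense to an annotated gene were kept out of the main test. That choice of classes was made after the table was seen. Genes with FPKM of at least 1 in at least 2 libraries were tested, which left 7835 genes, 176 of them small RNAs. These libraries could be of any group, so a gene near 0 in control cells could enter through the RNAi libraries where it rose. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with all 9 libraries in 1 model of 5 groups, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment at 0.05 within each comparison. The model had 4 residual degrees of freedom and 2.77 prior degrees of freedom. The E2F2 group has no replicate check, and its test borrows the spread of the other groups. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors of FPKM are SD over n = 2 libraries and errors of log2 changes are SE of the model.

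Each of the 4 RNAi groups and their mean was compared with the GFP group, and 4 differences between RNAi groups were tested in the same model. The 22 gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01 and adjusted over lists within a comparison, with an estimated correlation and fry as alternatives. The lists cover dREAM subunits, E2F family and RB regulators, DNA replication and S phase, G2 and mitosis, histones, chromatin and insulator factors, germline and piRNA pathway, testis-specific genes, ovarian follicle markers, RNA interference machinery, apoptosis and p53 response, hemocyte, neuronal, muscle, fat body and gut markers, immune and ecdysone genes, heat shock genes, glycolysis, cytosolic ribosomal proteins and proteasome subunits. fry asks whether the genes of a list move, on balance, in a common direction and makes no comparison with other genes. Overlaps between RNAi groups are given beside 100 simulations of unchanged groups sharing the same 2 control libraries. Genes with a neighbour on the opposite strand and 5′ ends at most 1000 bp apart were compared with other tested genes by Fisher's exact test.

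The comparisons, tests, gene lists, list of alternatives and rule for named genes were fixed before the data were examined. The rule takes the dREAM subunits; for each comparison with GFP, the 8 genes with the largest rise and the 8 with the largest fall among those past the test whose libraries do not overlap; up to 4 members of each list past the test, by size of change; and the 10 genes with the largest mean change per direction among those called in all of the 3 mip groups. It named 180 genes, of which those with the clearest place in a comparison are described. Small RNAs, which oligo-dT selection does not target, held 1, 2, 2, 4 and 0 of the 8 places for rises and 4, 1, 4, 7 and 2 of those for falls in mip40, mip120, mip130 and E2F2 RNAi and the mean of the 4. They are not named.

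The fit was tested on simulated data with the real genes' means and spreads and 200 genes changed by known folds. The changed genes were drawn from those whose mean log2(FPKM + 1) exceeded that of 5 FPKM, so the recovery of lower genes was not tested. Of genes changed by 2 times, 97.0% were recovered in each mip comparison, 89.6% in the E2F2 comparison and 98.5% in the mean of the 4. For changes of 1.5 times the shares were 74.6, 76.1, 92.5, 65.7 and 83.6% in mip40, mip120, mip130, E2F2 and the mean of the 4. False calls numbered 11 of 192, 10 of 190, 8 of 198, 6 of 175 and 11 of 198 in the same order.

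The alternatives were a pseudocount of 0.1 or 5, no filter, a mean FPKM of at least 5, quantile normalization, median-ratio scaling, fitting only the groups compared, no trend, robust moderation, the replicate number as a block, leaving out each library, and a change of at least 1. Known transcripts alone, transcripts in place of genes, leaving out small RNAs and leaving out genes listed at 0 in a group were added after seeing the data. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.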

Results

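Transcript levels were compared in Drosophila S2R+ cells in which subunits of dREAM were depleted by RNA interference (RNAi). dREAM is a chromatin-bound assembly of retinoblastoma-family, E2F, Myb and Myb-interacting proteins that represses genes of other cell types and regulates genes of the cell cycle. Of the 9 RNA libraries, 2 came from control cells given dsRNA against GFP, 2 each from mip40, mip120 and mip130 RNAi, and 1 from E2F2 RNAi. Values are FPKM as mean ± SD over n = 2 libraries, or the value of the single E2F2 RNAi library, and log2 changes are given ± SE. Sequencing depth is unknown, since the deposited values hold no counts. FPKM summed to between 618451 and 774009 per library. A single transcript of no annotated gene, starting at position 189620 of XHet, took from 2.52% to 16.1% of these sums, and annotated transcripts summed to between 588531 and 688463. Between 7350 and 7608 genes reached an FPKM of 1. Replicate libraries had Pearson r from 0.967 to 0.985 across 7835 genes, which are not independent replicates, and their median absolute difference ran from 0.09 to 0.11 on the log2 scale.

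Each targeted transcript fell in its own group. mip40 (2R, start 15179708) fell from 32.5 ± 2.04 FPKM in control cells to 1.29 ± 0.234 in mip40 RNAi, which left 3.96% (log2 change -3.88 ± 0.10, limma adjusted p = 6.4e-06). E2f2 (2L, start 21156232) fell from 26.9 ± 1.51 to 2.54 in E2F2 RNAi, which left 9.45% (-2.98 ± 0.12, limma adjusted p = 4.9e-05). mip130 (X, start 1802246) fell from 28.8 ± 1.5 to 4.73 ± 0.382 in mip130 RNAi, which left 16.4% (-2.38 ± 0.07, limma adjusted p = 6.7e-06). mip120 (2R, start 9393924) fell less, from 49.1 ± 4.87 to 29.3 ± 1.07 in mip120 RNAi, and 59.6% was left (-0.72 ± 0.10, limma adjusted p = 0.0026). The known mip120 isoform starting at 9393947 went from 12.8 and 12.2 FPKM in the control libraries to 3.49 and 3.16, and the more abundant isoform starting at 9393934 from 32.8 and 23.1 to 15.9 and 15.4. The other expressed isoforms did not fall, with start 9393935 at 3.73 and 4.53 in the control and 5.96 and 5.87 in mip120 RNAi, and start 9393924 at 3.16 and 5.78, then 3.16 and 5.58. In E2F2 RNAi the isoform starting at 9393934 was as low, at 15.6, while that starting at 9393947 stood at 15.1. The part of mip120 that the dsRNA matches is not given in the sources used here. EfTuM, a gene near mip120 picked after its values were seen, also fell in mip120 RNAi (log2 change -1.50 ± 0.09). Whether the dsRNA matches EfTuM could not be tested, so changes in mip120 RNAi cannot be assigned to mip120 alone.

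**Figure D1:**
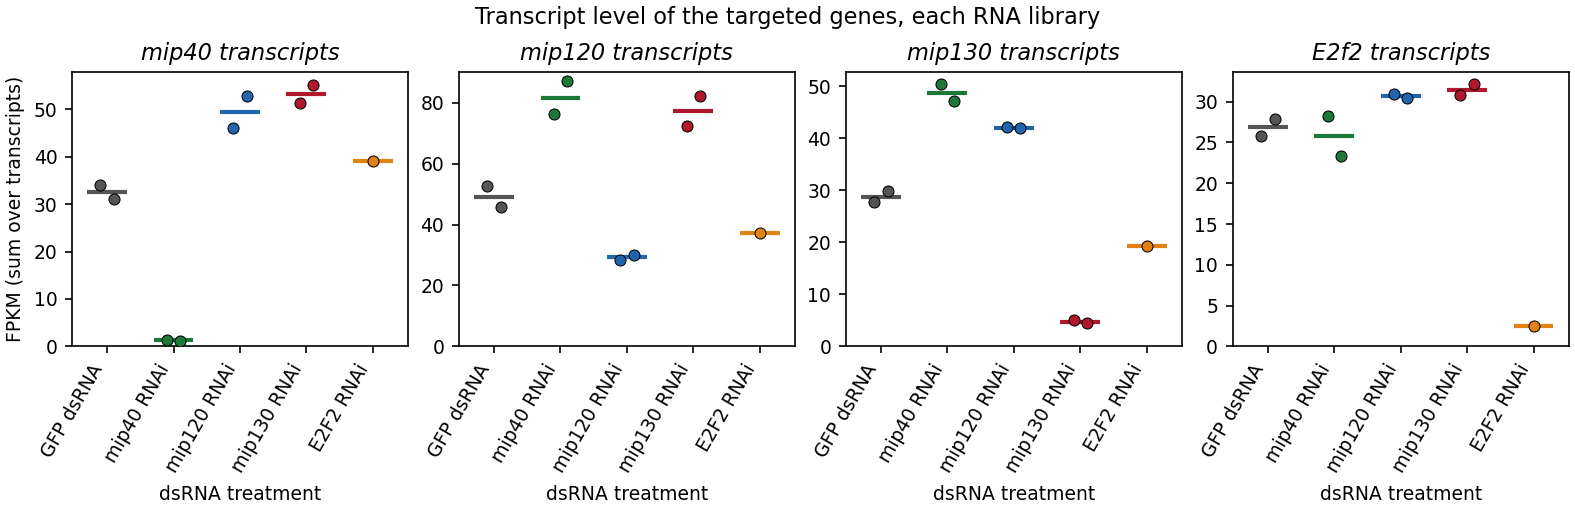
Transcript level of the 4 targeted genes in FPKM (vertical axes) in each RNA library (points) and as the group mean (lines), by dsRNA treatment (horizontal axes). Each transcript is lowest in its own RNAi group, at 1.29 FPKM for mip40, 29.3 for mip120, 4.73 for mip130 and 2.54 for E2f2.

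Transcripts of other subunits moved as well. mip130 rose from 28.8 ± 1.5 FPKM to 48.8 ± 2.34 in mip40 RNAi (log2 change 0.74 ± 0.07, limma adjusted p = 0.0018). It rose to 42.1 ± 0.0976 in mip120 RNAi (0.54 ± 0.07, limma adjusted p = 0.0022). mip40 rose to 49.4 ± 4.80 in mip120 RNAi (0.59 ± 0.10, limma adjusted p = 0.0056) and to 53.2 ± 2.70 in mip130 RNAi (0.69 ± 0.10, limma adjusted p = 0.0035). mip120 rose to 81.6 ± 7.64 in mip40 RNAi (0.72 ± 0.10, limma adjusted p = 0.0087) and to 77.2 ± 7.07 in mip130 RNAi (0.64 ± 0.10, limma adjusted p = 0.0048). In E2F2 RNAi mip130 fell to 19.3 (-0.55 ± 0.09, limma adjusted p = 0.014). Rbf, which encodes a retinoblastoma-family protein, rose from 26.4 ± 1.68 to 40.6 ± 1.16 in mip130 RNAi (0.60 ± 0.07, limma adjusted p = 0.0011). The gene Myb fell from 127 ± 9.08 to 85.8 ± 0.401 there (-0.55 ± 0.08, limma adjusted p = 0.003). Rbf2, the second retinoblastoma-family gene, rose from 5.24 ± 0.635 to 9.99 in E2F2 RNAi (0.82 ± 0.14, limma adjusted p = 0.015). Without GFP replicate 2, the limma adjusted p was 0.0543 for mip120 in mip40 RNAi, 0.0613 for mip130 in E2F2 RNAi and 0.0599 for Rbf2 in E2F2 RNAi. Of the 12 dREAM subunits, the targeted gene included, 2 rose and 1 fell in mip40 RNAi, 5 rose and 4 fell in mip120 RNAi, and 5 rose and 3 fell in mip130 RNAi. A further 2 rose and 2 fell in E2F2 RNAi, and 2 rose and 4 fell in the mean of the 4. Adjusted over the list alone, the counts were 4 and 1, 5 and 5, 5 and 4, 3 and 4, and 2 and 4. The list passed in none of the 5 comparisons (camera adjusted p = 0.39, 0.90, 0.68, 0.50 and 0.45).

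Listed at 0 in both control libraries, Gprk2 stood at 33.1 and 32.8 FPKM and CG3726 at 18.3 and 19.1 FPKM in mip40 RNAi. Sas, which encodes a sialic acid synthase, rose from 0.774 ± 0.440 FPKM to 32.3 ± 1.04 (log2 change 4.25 ± 0.15, limma adjusted p = 1.8e-05). There, the uncharacterised genes CG30383, CG34355 and CG15484 rose from 2.98 ± 1.58, 0.168 ± 0.0183 and 8.65 ± 0.548 FPKM to 51.2 ± 2.50, 10.8 ± 0.278 and 93.1 ± 13.4. Fewer genes fell by as much. CG11417 fell from 71.2 ± 2.43 to 17.8 ± 0.0821 (-1.94 ± 0.06, limma adjusted p = 1.3e-05). Also lower were miple, a midkine-like growth factor, from 4.69 ± 0.113 to 1.11 ± 0.313, and CG5036, from 5.83 ± 0.127 to 1.82 ± 0.00284. In all, 446 genes rose and 275 fell among 7835 tested (limma), 114 and 24 of them by at least 1 on the log2 scale.

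Some germline genes rose in mip40 RNAi. nos, a translational repressor of germ cells, rose from 0.345 ± 0.0163 to 10.3 ± 1.48 FPKM (3.06 ± 0.11, limma adjusted p = 1.7e-05). The piRNA-binding gene piwi rose from 0.598 ± 0.0184 to 6.90 ± 0.332 (2.30 ± 0.09, limma adjusted p = 2.2e-05). The differentiation factor bam rose from 1.43 to 7.02 ± 0.651, and the germline gap junction gene zpg from 0.382 ± 0.0558 to 2.36 ± 0.640. Of 35 germline and piRNA pathway genes, 14 rose and 1, squ, fell over all genes, and 17 rose and 3 fell adjusted over the list alone (median log2 change 0.25, camera adjusted p = 3.1e-05, adjusted p = 0.32 with an estimated correlation). Of 31 testis-specific genes in the table, only 6 passed the FPKM filter and were tested. Of these, 4 rose, and 5 adjusted over the list alone (median 0.50, camera adjusted p = 0.0018, adjusted p = 0.32 with an estimated correlation). Among them was the meiotic arrest gene topi, from 0.843 ± 0.179 to 2.67 ± 0.0810. vis, also among them, is nearly identical to its neighbour achi, and its level is uncertain. nos, piwi, zpg, topi and vis lay under 1 FPKM in control cells and entered the test only through RNAi libraries. Genes admitted in this way tilt their lists towards rises.

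Other lists passed as higher in mip40 RNAi with few of their genes past the test. Of 13 glycolysis genes, 3 rose, Pfk (phosphofructokinase, from 4.59 ± 0.759 to 19.8 ± 0.520 FPKM), Hex-A and Tpi, and 5 adjusted over the list alone (median 0.23, camera adjusted p = 0.0028, adjusted p = 0.32 with an estimated correlation). Of 47 replication genes, 6 rose, and 12 adjusted over the list alone (median 0.15, camera adjusted p = 4.3e-05, adjusted p = 0.32 with an estimated correlation). CG15220, a subunit of replication protein A, rose from 58.1 ± 0.815 to 88.8 ± 4.17 and DNA-ligI from 16.6 ± 0.347 to 22.8 ± 0.393. Of 84 cytosolic ribosomal protein genes, RpL18, RpS19b and RpL4 rose, 2 adjusted over the list alone (median 0.18, camera adjusted p = 4.3e-05, adjusted p = 0.80 with an estimated correlation, fry adjusted p = 0.18). RpL18 went from 241 ± 27.2 to 446 ± 54.0 (0.88 ± 0.14, limma adjusted p = 0.013, and 0.0753 without GFP replicate 2). Of 30 proteasome genes, the 2 that rose, over all genes and adjusted over the list alone, were Rpt3R (from 1.43 ± 0.0256 to 6.78 ± 0.0622) and Rpt6R (from 67.9 ± 2.88 to 102 ± 2.12), both relatives of general subunits with expression in testis (median 0.09, camera adjusted p = 0.041, adjusted p = 0.54 with an estimated correlation). Of 48 G2 and mitosis genes, 9 rose and 6 fell, 13 and 15 adjusted over the list alone, without a call (camera adjusted p = 0.75). The separase subunit gene thr rose from 9.04 ± 0.475 to 15.4 ± 0.207 and the kinesin gene pav fell from 46.4 ± 3.41 to 31.9 ± 1.11.

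The count of 721 changed genes in mip40 RNAi depended on single libraries. It was 306 without GFP replicate 1, 301 without GFP replicate 2, 329 and 439 without mip40 replicates 1 and 2, and 442 and 437 without mip120 replicates 1 and 2. When only the GFP and mip40 libraries were fitted it was 188. The camera adjusted p of the ribosomal list was 0.096 without GFP replicate 2 and 0.19 with quantile normalization. That of the proteasome list was 0.18 without GFP replicate 2, 0.22 without mip40 replicate 2 and 0.26 with quantile normalization.

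**Figure D2:**
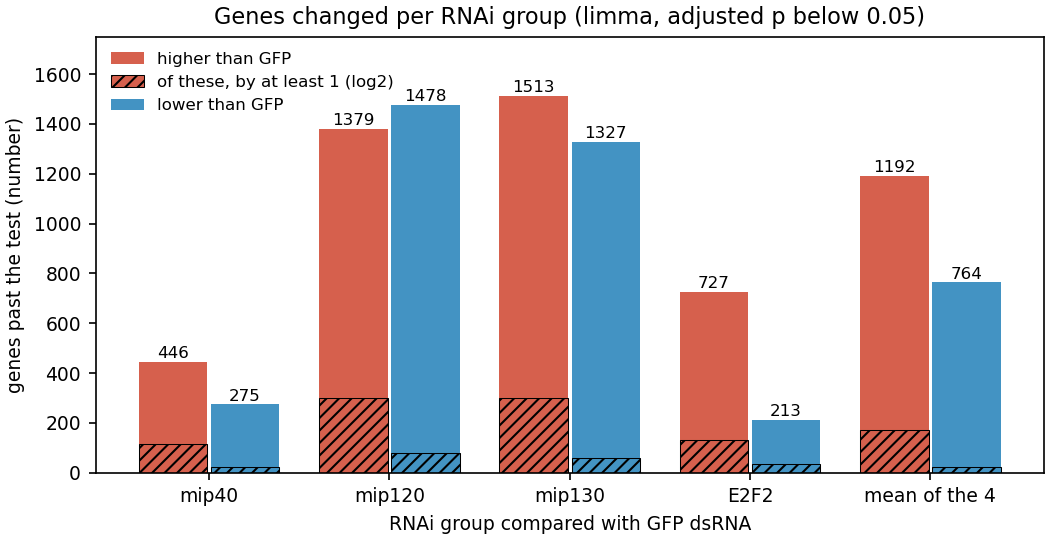
Number of genes past the test (vertical axis) that were higher or lower than in GFP dsRNA cells in each RNAi group and in the mean of the 4 (horizontal axis), with hatching for those changed by at least 1 on the log2 scale. mip120 and mip130 RNAi have the tallest bars, with 1379 and 1513 genes higher and 1478 and 1327 lower.

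In mip120 RNAi, CG14052 rose from 0.222 ± 0.0772 to 37.5 ± 1.1 FPKM (log2 change 4.98 ± 0.24, limma adjusted p = 3.4e-05). In the same group Sas rose from 0.774 ± 0.440 to 54.0 ± 0.169 (4.98 ± 0.15, limma adjusted p = 5.8e-06) and CG2887 from 0.071 ± 0.1 to 23.7 ± 0.880. CG8316, known as corolla, a part of the meiotic synaptonemal complex, rose from 0.487 ± 0.127 to 26.7 ± 1.1. The testis actin-related gene Arp53D was listed at 0 in both control libraries and at 19.9 and 24.0 in mip120 RNAi (limma adjusted p = 4.5e-06). Hexim, whose product inhibits the elongation factor P-TEFb, fell from 20.3 ± 0.612 to 1.28 ± 0.0550 (-3.22 ± 0.08, limma adjusted p = 4.2e-06). The gene rgn fell from 16.5 ± 3.15 to 3.28 ± 0.570, the microtubule regulator stai (stathmin) from 132 ± 4.75 to 32.6 ± 2.37 and the PDGF/VEGF-related ligand Pvf3 from 24.9 ± 2.14 to 5.69 ± 0.828. In all, 1379 genes rose and 1478 fell (limma), 302 and 81 by at least 1. With median-ratio scaling the balance turned, to 1540 and 1298, and with quantile normalization the counts were 1331 and 1650.

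Glycolysis genes rose together in mip120 RNAi, 10 of 13 over all genes and adjusted over the list alone (median 0.58, camera adjusted p = 7.1e-06, adjusted p = 0.31 with an estimated correlation). Pfk rose from 4.59 ± 0.759 to 37.6 ± 1.78 FPKM (2.79 ± 0.10, limma adjusted p = 8.2e-06). ImpL3, the lactate dehydrogenase gene, rose from 263 ± 12 to 828 ± 28.5 (1.65 ± 0.12, limma adjusted p = 0.00016) and Tpi from 63.0 ± 3.55 to 152 ± 5.35. Of 35 germline genes, 16 rose and 7 fell, 18 and 7 adjusted over the list alone (median 0.25, camera adjusted p = 0.0025, adjusted p = 0.47 with an estimated correlation). nos rose to 10.8 ± 0.155 and piwi to 12.6 ± 0.0129, while squ, bgcn, Hen1, rhi, aub, armi and egg fell. Of 6 testis-specific genes, topi, achi, mia and bol rose, over all genes and adjusted over the list alone (median 0.57, camera adjusted p = 0.038, adjusted p = 0.47 with an estimated correlation), topi to 3.20 ± 0.159.

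Mitotic genes moved apart in mip120 RNAi. The kinesin genes pav (46.4 ± 3.41 to 20.6 ± 0.204 FPKM, -1.13 ± 0.07, limma adjusted p = 0.00011), Klp67A (26.1 ± 1.93 to 12 ± 0.381), ncd (115 ± 3.11 to 58.1 ± 2.39) and Klp61F (63.6 ± 0.670 to 33.2 ± 0.924) fell, while thr rose to 17.5 ± 0.788 (0.88 ± 0.07, limma adjusted p = 0.00022). Of 48 G2 and mitosis genes, 22 fell and 10 rose, 24 and 10 adjusted over the list alone (median -0.21, camera adjusted p = 0.038, adjusted p = 0.47 with an estimated correlation). Of 19 hemocyte markers, 8 fell and 3 rose, 11 and 3 adjusted over the list alone (median -0.34, camera adjusted p = 0.019, adjusted p = 0.37 with an estimated correlation). Those that fell included the collagen IV genes Cg25C (20.1 ± 2.27 to 10.1 ± 0.421) and vkg (10.2 ± 1.11 to 5.10 ± 0.504), and the phagocytic receptor gene drpr rose from 3.70 ± 0.544 to 9.67 ± 0.749. Of 84 ribosomal protein genes, 10 rose, and 1 adjusted over the list alone (median 0.16, camera adjusted p = 0.019, adjusted p = 0.91 with an estimated correlation, fry adjusted p = 0.32).

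The count of 2857 changed genes in mip120 RNAi was 1836 without GFP replicate 2, 1889 without mip120 replicate 1 and 1581 without mip120 replicate 2. The camera adjusted p of the ribosomal list was 0.48 without GFP replicate 2 and 0.27 without mip120 replicate 2. The mitosis list had 0.053 without GFP replicate 2, 0.076 without mip120 replicate 1 and 0.096 with quantile normalization. The testis list had 0.051 without either mip40 library, 0.097 without mip120 replicate 1 and 0.12 with quantile normalization.

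In mip130 RNAi, Sas rose to 54.0 ± 1.98 FPKM (log2 change 4.98 ± 0.15, limma adjusted p = 6.2e-06), CG2887 to 24.2 ± 1.04 and nos to 22.5 ± 1.57 (4.12 ± 0.11, limma adjusted p = 3.1e-06). CG8788 rose from 0.552 ± 0.223 to 22.4 ± 0.138 and CG14516, a putative aminopeptidase gene, from 3.45 ± 0.249 to 63.3 ± 1.32. Hexim fell to 2.38 ± 0.186 (-2.66 ± 0.08, limma adjusted p = 5.2e-06), Pvf3 to 6.26 ± 0.634 and the piRNA pathway gene squ from 36.4 ± 0.782 to 11 ± 0.640. In all, 1513 genes rose and 1327 fell (limma), 300 and 61 by at least 1. With quantile normalization the balance turned, to 1307 and 1703, and with median-ratio scaling the counts were 1514 and 1398.

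Ribosomal protein genes rose in mip130 RNAi, 59 of 84 over all genes and 62 adjusted over the list alone (median 0.53, camera adjusted p = 1.1e-11, adjusted p = 0.43 with an estimated correlation). RpL18 rose from 241 ± 27.2 to 674 ± 17.7 FPKM (1.48 ± 0.14, limma adjusted p = 0.00064), RpL34a from 82.4 ± 12.7 to 169 ± 12.4 and RpS9 from 231 ± 47.0 to 453 ± 33.6. Of 30 proteasome genes, 12 rose, over all genes and adjusted over the list alone (median 0.19, camera adjusted p = 0.009, adjusted p = 0.43 with an estimated correlation). The testis relative Rpt3R was among them, at 6.89 ± 1.58, as were Rpt6R and Prosbeta2R2, relatives of the same kind. Prosbeta2R2 was listed at 0 in both control libraries and at 5.44 and 4.37 in mip130 RNAi. Of 13 glycolysis genes, 8 rose on both counts, over all genes and adjusted over the list alone (median 0.48, camera adjusted p = 0.0018, adjusted p = 0.43 with an estimated correlation), Pfk to 26.5 ± 0.0123. Of 47 replication genes, 17 rose and 4 fell on both counts, adjusted over the list alone included (median 0.13, camera adjusted p = 0.046, adjusted p = 0.43 with an estimated correlation). The clamp loader gene RfC3 rose from 17.4 ± 2.38 to 30.0 ± 2.94 and Gnf1, of the same complex, fell from 44.6 ± 4.31 to 28 ± 0.544.

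Of 35 germline genes, 20 rose and 5 fell in mip130 RNAi, 21 and 8 adjusted over the list alone (median 0.41, camera adjusted p = 0.00087, adjusted p = 0.43 with an estimated correlation), with piwi at 18.2 ± 1.41 FPKM. Of 6 testis-specific genes, topi, achi, mia and vis rose, over all genes and adjusted over the list alone (median 0.56, camera adjusted p = 0.047, adjusted p = 0.43 with an estimated correlation). Of 48 G2 and mitosis genes, 22 fell and 10 rose, 23 and 10 adjusted over the list alone (median -0.18, camera adjusted p = 0.046, adjusted p = 0.43 with an estimated correlation). In this group pav stood at 22.4 ± 1.21, Klp67A at 12.6 ± 0.677 and ncd at 58.5 ± 3.93, each below the control. Of 29 chromatin and insulator genes, 11 fell and 3 rose, 13 and 3 adjusted over the list alone (median -0.18, camera adjusted p = 0.0096, adjusted p = 0.43 with an estimated correlation). The insulator gene Cp190 fell from 98.7 ± 3.82 to 68.2 ± 1.61 and the remodeller gene Chd3 rose from 13.3 ± 0.866 to 26.4 ± 1.80. Of 19 hemocyte markers, 8 fell and 3 rose, as in mip120 RNAi, and 8 and 4 adjusted over the list alone. Here the list had no call (median -0.11, camera adjusted p = 0.44).

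The count of 2840 changed genes in mip130 RNAi was 1426 without GFP replicate 2 and 1495 without mip130 replicate 2. The camera adjusted p of the replication list was 0.089 without GFP replicate 1, 0.062 without either mip40 library, 0.054 without either mip120 library, and 0.051 and 0.052 without mip130 replicates 1 and 2. That of the testis list was 0.086, 0.063 and 0.064, 0.057 and 0.058, and 0.054 and 0.052 without the same libraries in that order, and 0.082 with quantile normalization. That of the mitosis list was 0.058 without GFP replicate 1, 0.057 and 0.058 without mip120 replicates 1 and 2, 0.051 and 0.052 without mip130 replicates 1 and 2, and 0.12 with quantile normalization.

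In the E2F2 RNAi library, Gprk2, CG3726 and Gcn2 stood at 33.9, 20.1 and 14.8 FPKM and were listed at 0 in both control libraries. The testis actin-related gene Arp53D was listed at 0 in both control libraries and at 14.4 FPKM in E2F2 RNAi (limma adjusted p = 4.1e-05). CG8316 (corolla) rose from 0.487 ± 0.127 to 12.6 (log2 change 3.20 ± 0.11, limma adjusted p = 4.1e-05). CG4623, a gene for a mitochondrial outer membrane protein, rose from 0.0805 ± 0.00505 to 10.6 (3.42 ± 0.16, limma adjusted p = 8.9e-05) and CG10307 from 0.221 ± 0.0143 to 9.71. FK506-bp2, a gene for a peptidyl-prolyl isomerase, fell from 768 ± 18.2 to 163 (-2.23 ± 0.10, limma adjusted p = 8.4e-05). CG43110 fell from 21.1 ± 1.89 to 7.50 and CG42494 from 3.19 ± 0.0843 to 0.355. In all, 727 genes rose and 213 fell (limma), 131 and 36 by at least 1, so that 77.3% of calls were rises. With quantile normalization 421 rose and 269 fell (61.0% rises), and with median-ratio scaling 487 rose and 296 fell (62.2% rises).

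Of 48 G2 and mitosis genes, 22 rose in the E2F2 RNAi library over all genes and 34 adjusted over the list alone (median 0.39, camera adjusted p = 7.4e-08, adjusted p = 0.15 with an estimated correlation). The kinetochore gene Ndc80 rose from 5.36 ± 0.659 to 12.9 FPKM (1.13 ± 0.16, limma adjusted p = 0.0091). Other rises were of thr to 19.5 (1.03 ± 0.08, limma adjusted p = 0.0011), the kinesin gene sub from 13.7 ± 0.599 to 27.9 and the separase gene Sse from 10.0 ± 1.29 to 18.1. Of 47 replication genes, 13 rose over all genes and 22 adjusted over the list alone (median 0.28, camera adjusted p = 0.00015, adjusted p = 0.44 with an estimated correlation). Fen1, a flap endonuclease gene, rose from 56.9 ± 3.25 to 111 (0.95 ± 0.11, limma adjusted p = 0.0047), CG15220 from 58.1 ± 0.815 to 103 and the primase gene DNApol-alpha50 from 10.9 ± 0.387 to 17.0. Of 20 apoptosis and p53 response genes, p53, Irbp, mre11, Ku80, RnrL and tefu rose, and 9 rose and 1 fell adjusted over the list alone (median 0.28, camera adjusted p = 0.010, adjusted p = 0.46 with an estimated correlation). Apart from p53, these act in DNA repair, its signalling or nucleotide supply. p53 rose from 6.21 ± 0.462 to 13.4, the Ku subunit gene Irbp from 22.3 ± 1.85 to 40.8 and mre11 from 46.1 ± 0.847 to 72.9. In mip40, mip120 and mip130 RNAi, 2, 6 and 8 of the 20 rose and 0, 4 and 3 fell, without a call (camera adjusted p = 0.52, 0.81 and 0.18). Adjusted over the list alone, 4, 6 and 9 rose and 0, 5 and 4 fell. There p53 stood at 8.89 ± 0.490, 14.8 ± 0.220 and 20.1 ± 2.40 and Irbp at 30.1 ± 0.781, 38.9 ± 1.08 and 40.8 ± 1.91, while mre11 stood at 50.7 ± 2.34, 42.1 ± 2.62 and 53.4 ± 2.04.

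Of 35 germline genes, 10 rose in E2F2 RNAi, and 13 adjusted over the list alone (median 0.23, camera adjusted p = 0.0012, adjusted p = 0.46 with an estimated correlation). The RNA helicase gene vas rose from 0.0701 ± 0.0622 to 6.48 FPKM (2.81 ± 0.23, limma adjusted p = 0.0011) and the piRNA pathway gene shu from 27.2 ± 0.237 to 66.2. Of 30 proteasome genes, 6 rose, and 13 adjusted over the list alone (median 0.21, camera adjusted p = 0.028, adjusted p = 0.46 with an estimated correlation). Pfk rose to 13.2 without a call of the glycolysis list (1 of 13 over all genes, 2 adjusted over the list alone, camera adjusted p = 0.82), and of 6 testis-specific genes 3 rose, 4 adjusted over the list alone, also without a call (camera adjusted p = 0.27). Of 19 hemocyte markers, 3 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.79). Pxn (peroxidasin) rose from 10.1 ± 0.718 to 42.5, while vkg fell from 10.2 ± 1.11 to 5.53 and Cg25C from 20.1 ± 2.27 to 12.3. The count of 940 changed genes was 507 without GFP replicate 1, 334 without GFP replicate 2, 516 and 519 without mip120 replicates 1 and 2, and 620 without mip130 replicate 2. It was 31 when only the GFP and E2F2 libraries were fitted. The camera adjusted p of the proteasome list was 0.056 without GFP replicate 2 and 0.17 with quantile normalization.

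**Figure D3:**
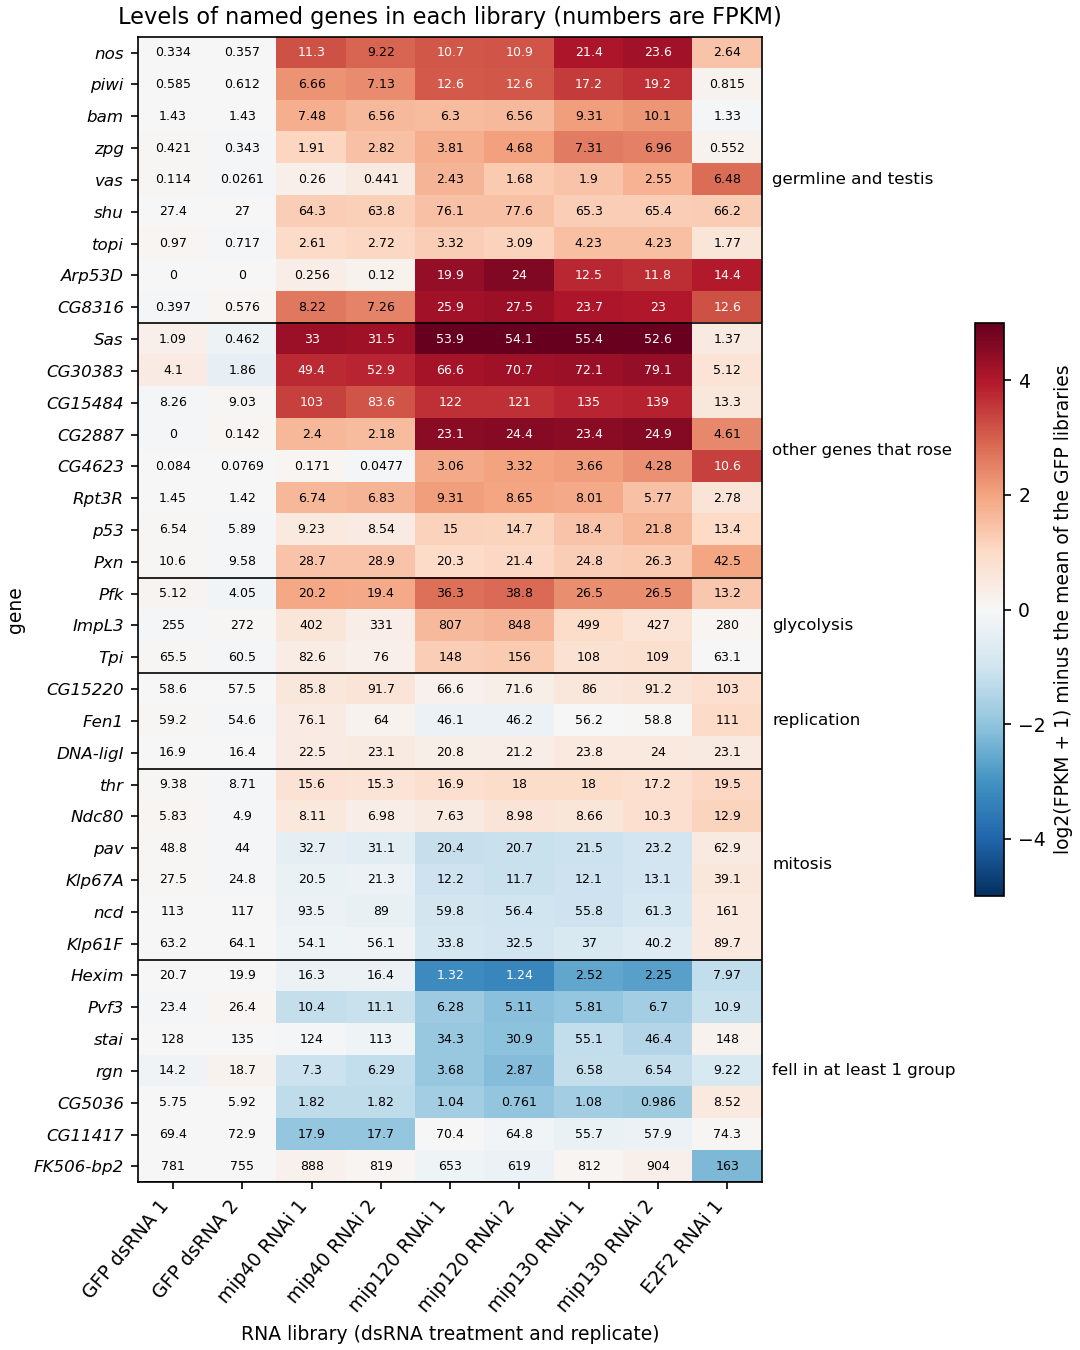
Level of named genes (vertical axis) in each RNA library (horizontal axis), with FPKM written in the cells and colour for log2(FPKM + 1) minus the mean of the GFP libraries. Sas lies at 0.462 and 1.09 FPKM in the GFP libraries, 1.37 in E2F2 RNAi and 31.5 to 55.4 in the mip libraries, and pav, Klp67A, ncd and Klp61F are lower than GFP in mip120 and mip130 RNAi and higher in E2F2 RNAi.

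In the mean of the 4 RNAi groups, Sas changed by 3.66 ± 0.12 on the log2 scale (limma adjusted p = 8.8e-06) and p53 by 1.03 ± 0.08 (limma adjusted p = 0.00028). Hexim changed by -1.86 ± 0.06 (limma adjusted p = 8.8e-06), Pvf3 by -1.51 ± 0.09 (limma adjusted p = 0.00011) and rgn by -1.28 ± 0.12 (limma adjusted p = 0.00075). In all, 1192 genes rose and 764 fell (limma), 171 and 22 by at least 1, so that 60.9% of calls were rises, against 48.8% (1005 and 1055) with quantile normalization. Germline genes rose (21 of 35, with 3 lower, and 21 and 5 adjusted over the list alone, median 0.31, camera adjusted p = 8.8e-05, adjusted p = 0.41 with an estimated correlation). Testis-specific genes rose too (4 of the 6 tested, 5 adjusted over the list alone, median 0.48, camera adjusted p = 0.0087, adjusted p = 0.41 with an estimated correlation). Glycolysis genes rose (8 of 13 on both counts, adjusted over the list alone included, median 0.38, camera adjusted p = 0.00021, adjusted p = 0.41 with an estimated correlation). Of 47 replication genes 16 rose and 1 fell, 20 and 2 adjusted over the list alone (median 0.14, camera adjusted p = 0.0029, adjusted p = 0.41 with an estimated correlation). Of 84 ribosomal protein genes 17 rose, 4 adjusted over the list alone (median 0.25, camera adjusted p = 2.6e-06, adjusted p = 0.68 with an estimated correlation, fry adjusted p = 0.064). Of 30 proteasome genes 8 rose on both counts, adjusted over the list alone included (median 0.12, camera adjusted p = 0.020, adjusted p = 0.41 with an estimated correlation). The count of 1956 genes was 1215 without GFP replicate 1 and 741 without GFP replicate 2. The proteasome list had a camera adjusted p of 0.078 without GFP replicate 2.

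**Figure D4:**
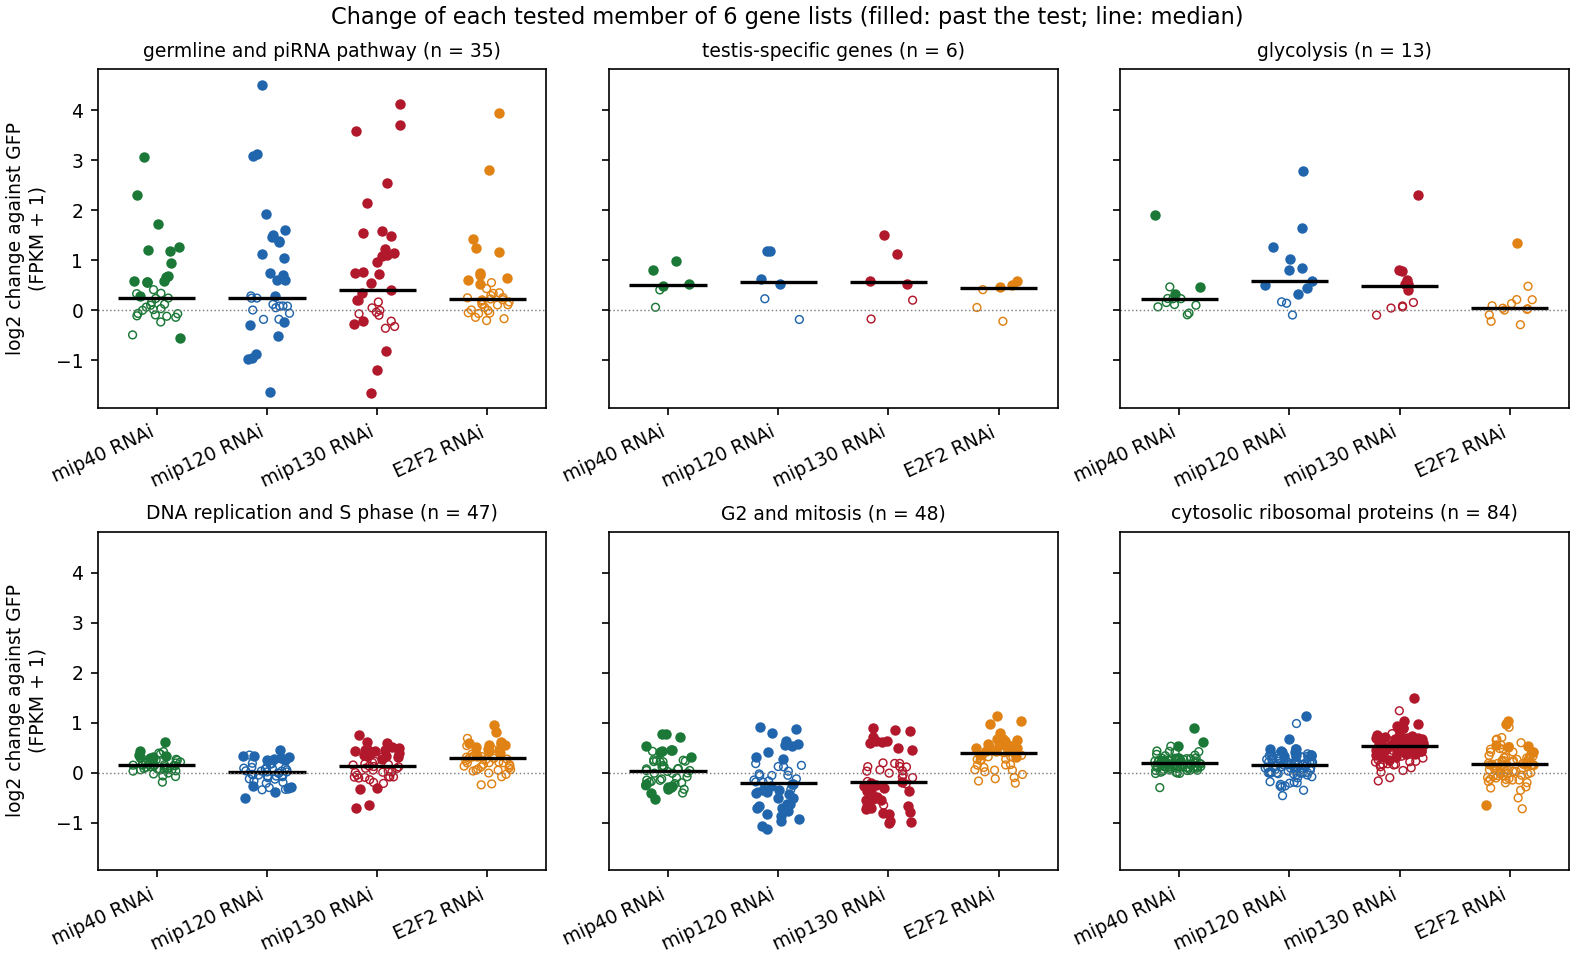
Log2 change against GFP dsRNA (vertical axes) of each tested member of 6 gene lists in the 4 RNAi groups (horizontal axes), with filled points for genes past the test and lines for medians. The median of the G2 and mitosis genes lies at -0.21 in mip120 RNAi, -0.18 in mip130 RNAi and 0.39 in E2F2 RNAi, and that of the ribosomal protein genes at 0.53 in mip130 RNAi.

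Another 11 lists passed in none of the 5 comparisons with GFP (camera). Their counts are given in the order mip40, mip120, mip130, E2F2 RNAi and mean of the 4, as genes higher then lower over all genes, and those adjusted over the list alone were the same unless stated. Of 10 E2F family and RB regulators, 0 and 0, 3 and 3, 2 and 2, 2 and 1, and 3 and 2 moved (0 and 0, 3 and 3, 2 and 3, 3 and 1, and 3 and 3 adjusted over the list alone), with Rbf2 among the rises and CycE among the falls in both mip120 and mip130 RNAi (smallest camera adjusted p = 0.36). Of 14 heat shock genes, 1 and 2, 4 and 3, 3 and 2, 0 and 0, and 4 and 3 moved (2 and 2 in mip40 RNAi adjusted over the list alone, smallest camera adjusted p = 0.43). Hsp27 and Hsp68 fell in each mip group, and Hsp22 rose from 32.2 ± 4.06 FPKM to 118 ± 10.8 in mip120 RNAi. Of 20 immune genes, 1 and 0, 2 and 6, 3 and 3, 0 and 0, and 2 and 3 moved (smallest camera adjusted p = 0.68). The dorsal gene, dl, rose from 16.5 ± 0.996 to between 31.9 ± 1.14 and 36.6 ± 0.561 in the mip groups. Of 12 ecdysone genes, 0 and 0, 1 and 4, 0 and 4, 0 and 0, and 0 and 2 moved (smallest camera adjusted p = 0.12), with the receptor gene EcR at 79.3 ± 11.2 in the control and 49.2 ± 2.02 in mip130 RNAi. Of 14 RNA interference genes, 0 and 0, 2 and 4, 1 and 4, 3 and 0, and 1 and 1 moved (1 and 0 in the mean adjusted over the list alone, smallest camera adjusted p = 0.18), with Dcr-1, drosha and armi lower in both mip120 and mip130 RNAi. Of 9 histone genes, 2 and 0, 2 and 1, 2 and 1, 0 and 0, and 2 and 0 moved (3 and 0 in mip40 RNAi adjusted over the list alone, smallest camera adjusted p = 0.30). The risers were the centromere histone gene cid and CG3509, the embryonic linker histone BigH1.

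Few markers of other cell types were expressed. Of 14 neuronal genes, 0 and 0, 2 and 1, 0 and 2, 0 and 0, and 1 and 1 moved in the same order (1 and 1, 0 and 1, and 0 and 1 adjusted over the list alone in mip120 and mip130 RNAi and the mean, smallest camera adjusted p = 0.37), with Syx1A lower in mip120 and mip130 RNAi. Of 5 muscle genes, TpnC41C rose in mip120 RNAi, and in the mean 1 rose and 1 fell adjusted over the list alone (smallest camera adjusted p = 0.79). Of 3 ovarian follicle genes, 1 rose in each comparison, fs(1)Yb in the mip groups and the mean and Cp15 in E2F2 RNAi (smallest camera adjusted p = 0.34). The single tested fat body gene, Gbp, fell in all 5 comparisons (smallest camera adjusted p = 0.084) and the single tested gut gene, LM408, in all but E2F2 RNAi (smallest camera adjusted p = 0.050). Counts of these marker lists adjusted over the list alone were otherwise those over all genes.

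Differences between RNAi groups were tested directly. Hexim was higher in mip40 than in mip120 RNAi by 2.93 ± 0.08 on the log2 scale (limma adjusted p = 6.4e-06), and CG11417 was lower, with a difference of -1.87 ± 0.06 (limma adjusted p = 1.9e-05). CG2887 was also lower in mip40 RNAi, with differences of -2.91 ± 0.10 from mip120 RNAi (limma adjusted p = 1.8e-05) and -2.94 ± 0.10 from mip130 RNAi (limma adjusted p = 1.7e-05). In all, 1124 genes were higher and 877 lower in mip40 than in mip120 RNAi (894 and 1050 with median-ratio scaling), and 994 higher and 962 lower than in mip130 RNAi. G2 and mitosis genes were higher in mip40 RNAi than in mip120 RNAi (22 of 48 with 3 lower, 24 and 4 adjusted over the list alone, camera adjusted p = 9.7e-05, adjusted p = 0.14 with an estimated correlation). The same held against mip130 RNAi (23 with 2 lower on both counts, adjusted over the list alone included, camera adjusted p = 0.00012, adjusted p = 0.45 with an estimated correlation). Against mip120 RNAi, glycolysis genes were lower in mip40 RNAi (7 of 13, 8 adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.14 with an estimated correlation). Hemocyte markers were higher (12 of 19, with 12 and 1 adjusted over the list alone, camera adjusted p = 0.00068, adjusted p = 0.14 with an estimated correlation). Chromatin genes were higher in mip40 than in mip120 RNAi (9 of 29, 11 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.65 with an estimated correlation, and 0.077 with quantile normalization). Replication genes were also higher (13 of 47 with 1 lower, 14 and 1 adjusted over the list alone, camera adjusted p = 0.0022, adjusted p = 0.37 with an estimated correlation). Chromatin genes were also higher than in mip130 RNAi (14 of 29 with 1 lower, 18 and 3 adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.59 with an estimated correlation). Against mip130 RNAi, ribosomal protein genes were lower (29 of 84, 32 adjusted over the list alone, camera adjusted p = 1e-06, adjusted p = 0.70 with an estimated correlation). Without mip40 replicate 1, mip120 replicate 1 and mip120 replicate 2 the count of 2001 genes that differed between mip40 and mip120 RNAi was 838, 963 and 516. That of 1956 between mip40 and mip130 RNAi was 334 and 1077 without mip40 replicates 1 and 2, and 679 and 198 without mip130 replicates 1 and 2. With only the groups compared in the fit, the counts were 1332 and 1033.

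mip120 and mip130 RNAi differed in fewer genes, with 265 higher and 387 lower in mip120 RNAi (limma; 405 and 397 with quantile normalization, 401 and 364 with median-ratio scaling). nos was lower in mip120 RNAi, with a difference of -0.99 ± 0.11 (limma adjusted p = 0.0053) and ImpL3 higher by 0.84 ± 0.12 (limma adjusted p = 0.013). Ribosomal protein genes were lower in mip120 RNAi as a list, with few past the test over all genes (6 of 84, 39 adjusted over the list alone, camera adjusted p = 1.8e-11, adjusted p = 0.67 with an estimated correlation). Glycolysis genes were higher there (6 of 13 on both counts, adjusted over the list alone included, camera adjusted p = 0.0002, adjusted p = 0.27 with an estimated correlation). Hemocyte markers were lower in mip120 RNAi (7 of 19, 11 adjusted over the list alone, camera adjusted p = 0.0002, adjusted p = 0.23 with an estimated correlation). Also lower there as lists, with few genes past the test over all genes, were replication genes (5 of 47, 8 adjusted over the list alone, camera adjusted p = 0.00096, adjusted p = 0.35 with an estimated correlation) and proteasome genes (4 of 30, 14 adjusted over the list alone, camera adjusted p = 0.0002, adjusted p = 0.35 with an estimated correlation). The count of 652 genes was 71 and 105 without mip120 replicates 1 and 2, and 193 and 79 without mip130 replicates 1 and 2, and 155 when only these groups were fitted.

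Between the E2F2 RNAi library and the mean of the 3 mip groups, 1527 genes were higher and 762 lower in E2F2 RNAi (limma; 1076 and 958 with quantile normalization, 985 and 1078 with median-ratio scaling). Sas, piwi and FK506-bp2 were lower in E2F2 RNAi, with differences of -4.30 ± 0.16 (limma adjusted p = 2.5e-05), -2.81 ± 0.09 (limma adjusted p = 1.8e-05) and -2.24 ± 0.09 (limma adjusted p = 3.1e-05). In turn vas was higher by 1.67 ± 0.20 (limma adjusted p = 0.0026) and pav by 1.33 ± 0.08 (limma adjusted p = 0.00017). G2 and mitosis genes were higher in E2F2 RNAi (29 of 48, with 35 higher and 1 lower adjusted over the list alone, median 0.44, camera adjusted p = 4.3e-08, adjusted p = 0.14 with an estimated correlation). Glycolysis genes were lower (8 of 13, 9 adjusted over the list alone, median -0.34, camera adjusted p = 3.9e-05, adjusted p = 0.21 with an estimated correlation). Ribosomal protein genes were lower on balance (12 lower and 4 higher of 84, 7 and 1 adjusted over the list alone, median -0.11, camera adjusted p = 0.0011, adjusted p = 0.94 with an estimated correlation). Against GFP their median was 0.16 in E2F2 RNAi, 0.18 in mip40 RNAi, 0.16 in mip120 RNAi and 0.53 in mip130 RNAi, so the difference came mainly from mip130 RNAi.

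Calls were shared between the groups, which were all compared with the same 2 control libraries. mip120 and mip130 RNAi shared 992 rises and 869 falls, where independent lists would share 266 and 250. mip40 RNAi shared 373 rises and 213 falls with mip120 RNAi (independent lists, 78.5 and 51.9) and 383 and 203 with mip130 RNAi (86.1 and 46.6). E2F2 RNAi shared 200 rises and 44 falls with mip40 RNAi (41.4 and 7.48), 321 and 69 with mip120 RNAi (128 and 40.2) and 369 and 84 with mip130 RNAi (140.4 and 36.1). Calls in opposite directions were fewer than independent lists would give, and the shared controls can lower their number. Another 101 genes fell in mip120 RNAi and rose in E2F2 RNAi (independent lists, 137) and 22 did the reverse (37.5). For mip130 and E2F2 RNAi the numbers were 48 (123) and 19 (41.1). In all of the 3 mip groups 356 genes rose and 179 fell (independent lists, 15.2 and 8.79), and in all 4 groups 165 and 31 (1.41 and 0.239). Among 100 simulations of unchanged groups the mean number shared by the 3 mip groups was 0. Unchanged groups yield almost no calls to share, so this number cannot show how many real calls the shared controls make coincide. Across genes, which are not independent replicates, log2 changes in mip120 and mip130 RNAi had r = 0.77 and a covariance of 0.268, against 0.50 and 0.032 in the simulations. For mip40 with mip120 and mip130 RNAi r was 0.54 and 0.56 (simulated 0.49 and 0.50) and the covariance 0.141 and 0.147 (simulated 0.031 and 0.032). For E2F2 with mip40, mip120 and mip130 RNAi r was 0.33, 0.21 and 0.25 (simulated 0.41, 0.42 and 0.40) and the covariance 0.0824, 0.068 and 0.084 (simulated 0.032, 0.033 and 0.032). Part of the excess of shared calls over independent lists may come from the shared controls, since 2 control libraries are too few to split. The covariance exceeded the simulated one by 0.236 for mip120 with mip130 RNAi, by 0.109 and 0.115 for mip40 with mip120 and mip130 RNAi, and by 0.0508, 0.0355 and 0.0523 for E2F2 with mip40, mip120 and mip130 RNAi. The simulations drew independent noise for each library. A bias common to both control libraries is therefore not in them and may be part of this excess. The 535 genes called in 1 direction in the 3 mip groups were 258 without GFP replicate 1, 236 without GFP replicate 2, 266 and 320 without mip40 replicates 1 and 2, and 339 and 327 without mip120 replicates 1 and 2. They were 150 when only the groups compared were fitted.

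Genes arranged head to head with a neighbour were compared with other genes. In the mean of the 4 RNAi groups, 16.8% of 3581 genes with a divergent neighbour rose, against 14.4% of 4076 other tested genes (odds ratio 1.20, Fisher's exact test, adjusted p = 0.0056), and 8.24% against 11.2% fell (odds ratio 0.71, Fisher's exact test, adjusted p = 5.6e-05). In mip40 RNAi the odds ratios were 1.38 for rises (Fisher's exact test, adjusted p = 0.0024) and 0.53 for falls (adjusted p = 1.1e-05), and in mip120 RNAi 1.19 (adjusted p = 0.0056) and 0.84 (adjusted p = 0.0055). In mip130 RNAi they were 1.24 (Fisher's exact test, adjusted p = 0.00075) and 0.90 (adjusted p = 0.12), and in the E2F2 RNAi library 1.13 (adjusted p = 0.14) and 0.81 (adjusted p = 0.17). With neighbours within 500 bp, the odds ratio for falls in mip130 RNAi was 0.82 (Fisher's exact test, adjusted p = 0.0031) and that for rises in E2F2 RNAi 1.21 (adjusted p = 0.019), both past the threshold. The test treats neighbouring genes as independent. It does not match the genes by expression level, on which the chance of a call can depend.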

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

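The test of transcripts outside the annotated genes was chosen only after the table was seen, as were the transcripts named here. These transcripts enter none of the comparisons above, and some lay above their level in the control libraries. Of 467 tested transcripts of no annotated gene, 15 rose in mip40 RNAi, 60 in mip120 RNAi, 67 in mip130 RNAi and 15 in E2F2 RNAi (limma), and 9, 52, 47 and 9 fell. Of 119 transcripts antisense to an annotated gene, 8, 24, 24 and 9 rose in the same order, and 2, 20, 18 and 1 fell. Of the 7835 genes of the main test, 446, 1379, 1513 and 727 rose and 275, 1478, 1327 and 213 fell. Each is a larger share than among the transcripts of no annotated gene. A transcript antisense to CG6865 (3L, start 18857364) stood at 0.131 and 0.0481 FPKM in the control libraries, 13.7 and 13.6 in mip120 RNAi, 9.12 and 13.1 in mip130 RNAi, 3.39 and 3.26 in mip40 RNAi and 0.471 in E2F2 RNAi. A transcript of no annotated gene on X (start 9056161) went from 3.20 and 3.74 to 26.1 and 27.2 in mip120 RNAi and 21.4 in E2F2 RNAi. Another on X (start 10279861) was listed at 0 in both control libraries and at 27.3 and 21.6 in mip120 RNAi. A transcript antisense to Ac3 (2L, start 21637692) went from 38 and 31.1 to 6.49 and 5.61 in mip120 RNAi. The strand setting of the libraries is not given in the sources used here, so antisense levels are uncertain. No biological explanation was tested.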

How the results depend on the processing

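Known transcripts alone, transcripts in place of genes, and leaving out small RNAs or genes listed at 0 were chosen after the data were seen. No named change and no list call against GFP reversed its direction under the alternatives run on it, which are given next. Of 101 named changes, 101 stayed past the threshold with a pseudocount of 0.1, quantile normalization and the replicate block, and 97 did so without each library. All 101 were past the threshold in the main fit and were mostly picked by size. Their stability therefore does not carry over to the other calls. Of 31 list calls, 0 passed with an estimated correlation (fry called 50, 28 of them shared, and lost the ribosomal list in mip40 RNAi, mip120 RNAi and the mean), 24 passed with quantile normalization, 28 with the replicate block and 21 without each library.

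Counts of changed genes ran, without each library in turn, from 301 to 719 in mip40 RNAi, 1581 to 2857 in mip120 RNAi, 1426 to 2839 in mip130 RNAi, 334 to 934 in E2F2 RNAi and 741 to 1859 in the mean of the 4. Differences ran from 516 to 1994 (mip40 to mip120), 198 to 1954 (mip40 to mip130) and 71 to 660 (mip120 to mip130), and 1700 to 2314 for E2F2 against the mips. Shared mip calls ran from 236 to 405 and list calls from 25 to 30. Fewer libraries leave fewer residual degrees of freedom, and a lone library is assumed to vary like the other groups.

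Fitting only the groups compared, which leaves fewer samples, gave 188 (mip40), 31 (E2F2), 1332 (mip40 to mip120), 1033 (mip40 to mip130), 155 (mip120 to mip130) and 150 (shared by the mips). A required change of at least 1 left 138, 383, 361, 167 and 193 for mip40, mip120, mip130, E2F2 and the mean, and 147, 164, 61 and 303 for the 4 differences in the order above. Transcripts in place of genes gave 195, 1773, 1811, 325, 824, 798, 610, 70 and 1350 in that order, known transcripts alone 444 (mip40) and 355 (shared), and no filter 1292 (mip40 to mip130) and 421 (mip120 to mip130), and the cause was not tested.

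Same-numbered libraries did not deviate together (correlations from -0.135 to 0.0212), so the numbers do not pair them. With the replicate block the counts were 414 (mip40), 411 (E2F2), 1272 (mip40 to mip130), 211 (mip120 to mip130), 1472 (E2F2 against the mips) and 340 (shared). The block took mip130 RNAi's replication, mitosis and testis lists to a camera adjusted p of 0.052, and the cause was not tested. A count test was not run, since FPKM hold no reads, and unknown depth limits what low genes can show.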

Other observations

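The tests of the mip40 transcript left and of genes downstream of silent genes, and the genes of the next paragraph were chosen after their values were seen.

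EfTuM is a mitochondrial translation elongation factor gene on the same strand as mip120. Its start (2R, 9395063) lies 1139 bp downstream of the outermost mip120 start, and a known mip120 isoform starts beyond it, at 9397123. That isoform was listed at 0 in every library but E2F2 RNAi (0.353). EfTuM fell from 87.8 ± 6.20 FPKM (SD, n = 2) to 30.5 ± 3.52 in mip120 RNAi (limma adjusted p = 7.5e-05). It stood at 52.6 ± 0.334 in mip40 RNAi, 50.6 ± 0.531 in mip130 RNAi and 124 in E2F2 RNAi. Whether the mip120 dsRNA matches EfTuM, or reads were divided wrongly between these genes, could not be tested. Genes listed at 0 in all GFP, mip120 and mip130 libraries were CG3726 on X and a group of neighbours on 3R, and an exact 0 can be a failed estimate. CG3726 (start 5811194) stood at 18.3 and 19.1 FPKM in mip40 RNAi and 20.1 in E2F2 RNAi. Gprk2 (start 27230967) stood at 33.1 and 32.8 and at 33.9, Gcn2 (start 27221382) at 11.9 and 11.9 and at 14.8, and CG11337 (start 27231174) at 8.64 and 10.9 and at 11.1. Hsp26 was listed at 0 in the GFP, mip40 and E2F2 libraries and at 5.62 and 5.81 in mip120 RNAi and 2.96 and 5.67 in mip130 RNAi.

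G2 and mitosis genes went apart between groups, with 43 of 48 above 0 in the E2F2 RNAi library and 32 of 48 below 0 in the mean of mip120 and mip130 RNAi. With quantile normalization their median log2 change in E2F2 RNAi was 0.29 (bootstrap SE 0.0463), against 0.39 as deposited, which argues against the scaling of that library as the whole cause. In mip120 and mip130 RNAi the median was -0.154 as deposited (bootstrap SE 0.0871) and -0.156 with quantile normalization (0.0851), so the fall kept its size with this rescaling. The limit set beforehand asked for a margin of the bootstrap SE, which the fall did not reach, so that test did not decide. The bootstrap SE is a spread over the list's genes, resampled as if independent, and does not measure an effect of scaling. The camera calls lost with quantile normalization weigh the list against all genes, whose median went from -0.04 to -0.05 in mip120 RNAi and from 0.01 to -0.05 in mip130 RNAi. Why these calls were lost was not tested. Replicate libraries of a group differed in the list's median by at most 0.0237, yet the state of the single E2F2 culture cannot be told apart from the depletion of E2F2.

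Fewer genes were called in mip40 RNAi (721) than in mip120 and mip130 RNAi (2857 and 2840). The mip40 transcript left was 3.96%, below the 59.6% and 16.4% left of mip120 and mip130, which argues against a less complete loss of the transcript, while protein was not measured. Over 1861 genes called in 1 direction in mip120 and mip130 RNAi, the median change in mip40 RNAi was 41.7% of the mean of theirs. These genes were picked by their calls in mip120 and mip130 RNAi, which raises the values there, so the share does not decide on spread. The model gave each gene the same SE in the 3 mip comparisons. A larger spread between the mip40 libraries would therefore widen the SE of all 3 alike.

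The start of Hexim lies 2522 bp downstream of the start of CG3505 on the same strand (3R, starts 10485163 and 10482641). CG3505 rose from 0.855 ± 0.172 FPKM (SD, n = 2) to 12.6 ± 0.0307 in mip120 RNAi, 12.6 ± 0.722 in mip130 RNAi, 14.7 in E2F2 RNAi and 5.27 ± 0.309 in mip40 RNAi. Hexim, at 20.3 ± 0.612 in the control, stood at 1.28, 2.38, 7.97 and 16.3 in the same order, so the largest rise was not in the group with the largest fall. A candidate explanation is that a gene next downstream falls when a silent gene is switched on. With Hexim left out, the odds ratio of a fall next after any gene that rose by at least 1 was 0.88 in mip120 RNAi (26 of 149, 95% interval 0.55 to 1.36, Fisher's exact test, p = 0.60), 1.85 in mip40 RNAi (0.36 to 5.87), 0.90 in mip130 RNAi (0.56 to 1.40) and 1.17 in E2F2 RNAi (0.14 to 4.54). After genes under 1 FPKM in control cells it was 1.06 in mip120 RNAi (14 of 69, 0.54 to 1.95, Fisher's exact test, p = 0.88), 1.19 in mip40 RNAi (0.029 to 7.46), 0.69 in mip130 RNAi (0.33 to 1.32) and 0 in E2F2 RNAi (0 of 24, 0 to 5.89), and as each interval spans 1 the explanation stays open.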
